A study of Homo sapiens with 4 samples.

How the data were processed

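Gene expression was measured in 4 HCT116 samples on one-colour Agilent arrays. Per the labels' protocols, total RNA was extracted with RNeasy kits and labelled with Cy3 by the one-colour Quick Amp method. The spot intensity values of each scanner file were made by the authors with Agilent Feature Extraction, version 10.7.3.1 per the file headers, while the submitters' processing notes name version 9.1. Per the file headers, the processed signal had been background-subtracted and detrended within each array, with surrogate values for dim spots, and had not been normalized between arrays. The deposited value table holds log2 values which, compared with the scanner files, were scaled by the authors near each array's 75th percentile and centred on each probe's median over the 4 arrays. Probe positions refer to genome build hg18, per the file headers.

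The scanner files were read in R 4.3.3 with the packages jsonlite (2.0.0) and data.table (version 1.17.8). Each array held 43118 spots that were not controls and 1377 control spots. The control spots, and spots marked as outliers by Feature Extraction, were left out, and repeated spots of a probe were averaged. The 75th percentile intensity was 1316, 1331.63, 1404.64 and 1406.47 on the no-siRNA, control-siRNA, siRNA 1 and siRNA 2 arrays, and all values were log2 processed signal minus the log2 of the array's 75th percentile. Of 34127 probes, 24827 were named through their accession, 1276 through a current symbol and 500 through a synonym, and 7524 kept the name in the file. A gene was tested where a probe was well above background on both arrays of at least 1 group, and was represented by its brightest such probe. This left 16528 genes, of which 13808 had a current symbol and 15663 were well above background on all 4 arrays.

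Knockdown (siRNA 1 and siRNA 2, n = 2) was compared with control (no siRNA and control siRNA, n = 2) with limma 3.58.1 (lmFit and eBayes), and p-values were adjusted by the Benjamini-Hochberg method over all genes. The prior had 2.47 degrees of freedom beside 2 residual degrees of freedom. As a rule of size, genes at least 2-fold apart in all 4 knockdown-control array pairs were counted, beside the same count in the other splits of the arrays. Single arrays were compared by size alone, at 2-fold. The differences under each siRNA were correlated across genes and set beside 100 simulations of unchanged groups that share the control arrays. In the self-test on simulated data, limma called 0 of 67 genes with a 2-fold difference, 37 of 67 with 4-fold and 60 of 66 with 8-fold, and 4 of 16284 unchanged genes. The 2-fold rule picked 9, 64 and 66 of the changed genes and 63 of the unchanged ones.

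The 30 gene lists covered ERK pathway output, MAP kinase phosphatases, MAP kinases and their kinases, AP-1 family and stress early genes, p53 targets, G1/S and DNA replication, G2/M and mitosis, CDK inhibitors and G1 cyclins, interferon-stimulated genes, NF-kB targets, WNT targets, TGF-beta and BMP targets, YAP and SRF targets, and EGF receptor family and ligands. They also covered extracellular proteolysis and invasion, integrins and laminins, mesenchymal genes, epithelial junction and keratin genes, intestinal differentiation, apoptosis regulators, endoplasmic reticulum and integrated stress, heat shock, NRF2 targets, hypoxia and glycolysis, cholesterol synthesis, fatty acid synthesis, short-interfering RNA machinery, fibroblast markers, blood and immune cell markers, and reference genes. Each was tested with limma's camera at a preset correlation of 0.01, adjusted over the lists, and also with an estimated correlation and with fry. For single arrays, list medians were set beside 10000 random lists matched on signal. These draw each gene separately and do not allow for genes that vary together. The lists, the tests of the comparisons, the thresholds and the alternatives were chosen before the data were examined, except where a test or an alternative is said to have been added later.

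The genes named were chosen by a fixed rule. It took DUSP4, and then the 12 highest and 12 lowest genes past an adjusted p of 0.05 and well above background on all 4 arrays, filled up with the largest differences without overlap between groups where fewer passed. It added up to 3 genes per direction that were well above background in 1 group only, given as lower bounds on the fold. It also took up to 4 members of each list by size and the 5 highest and 5 lowest genes of each comparison of single arrays. Genes without a symbol were counted and not named, and the values of some genes that the rule picked are not shown. Where a call is described by the members past the threshold in their list, those genes were added after their values were seen.

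The alternatives were normexp background correction (offset 50) with quantile normalization, centring on the median, quantile normalization of the processed signal, the deposited table's values, no filter on dim probes, a filter requiring all 4 arrays, the mean of a gene's probes, and leaving out each array in turn. Others were a trended and robust variance prior, an adjusted p of 0.10, fold minimums of 1.5 and 3, and split controls for the correlation. An alternative without the first 10 columns of spots, at the low-numbered side of the array, was added after the data were seen, and so were the simulated and split-control counts of genes shared between the siRNAs and the shares with the same sign beside them. A block for slide was not run because all 4 arrays lay on 1 slide, so array position and sample cannot be separated. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.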

Results

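The series addressed which genes depend on DUSP4 in HCT116, an established human colorectal carcinoma cell line. DUSP4 is a dual-specificity phosphatase of the nucleus that removes activating phosphates from MAP kinases such as ERK and JNK. Its transcript was targeted with small interfering RNA (siRNA), a short double-stranded RNA that directs the cell's own machinery to degrade a matching transcript. Total RNA from 4 samples was hybridised to 4 one-colour Agilent expression arrays. The control group held 1 sample without siRNA and 1 sample with a control siRNA (n = 2), and the knockdown group held 1 sample for each of 2 DUSP4 siRNAs (n = 2). Of 43118 spots that were not controls, 63.7% and 63.5% lay well above background on the no-siRNA and control-siRNA arrays, and 62.7% and 62.9% on the arrays labelled DUSP4 siRNA 1 and 2. No spot was saturated. Each of the 4 samples had its own treatment, and no treatment was repeated. The p-values therefore measure the spread between differently treated samples within a group, not between replicate cultures. Differences of treatment, culture and array cannot be separated in that spread. The small number of arrays limits the precision. Levels are log2 intensities relative to the array's 75th percentile.

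DUSP4 itself was lower on both knockdown arrays than on both controls. The array carried 1 DUSP4 probe (A_23_P134935, for NM_001394), whose target lies on chromosome 8 at 29250301 to 29250360 in genome build hg18. Its level was 2.06 without siRNA and 2.26 with control siRNA, against 0.68 on the array labelled siRNA 1 and -0.03 on the array labelled siRNA 2. The group means were 2.16 ± 0.14 (SD, n = 2) and 0.32 ± 0.50 (SD, n = 2), a log2 difference of -1.83 with SE 0.284 and 95% confidence interval -2.59 to -1.08, or 3.56-fold. After adjustment over all genes this difference did not pass 0.05 (limma, adjusted p = 0.113). Relative to the control mean, DUSP4 was 2.79-fold lower on the siRNA 1 array and 4.55-fold lower on the siRNA 2 array. Without the siRNA 1 array the log2 difference was -2.19 (limma, adjusted p = 0.00388) and without the siRNA 2 array -1.48 (limma, adjusted p = 0.0194). Both p-values rest on a knockdown group of 1 array, which is assumed to vary like the controls. Without the no-siRNA or the control-siRNA array the limma adjusted p was 0.592 and 0.671.

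**Figure D1:**
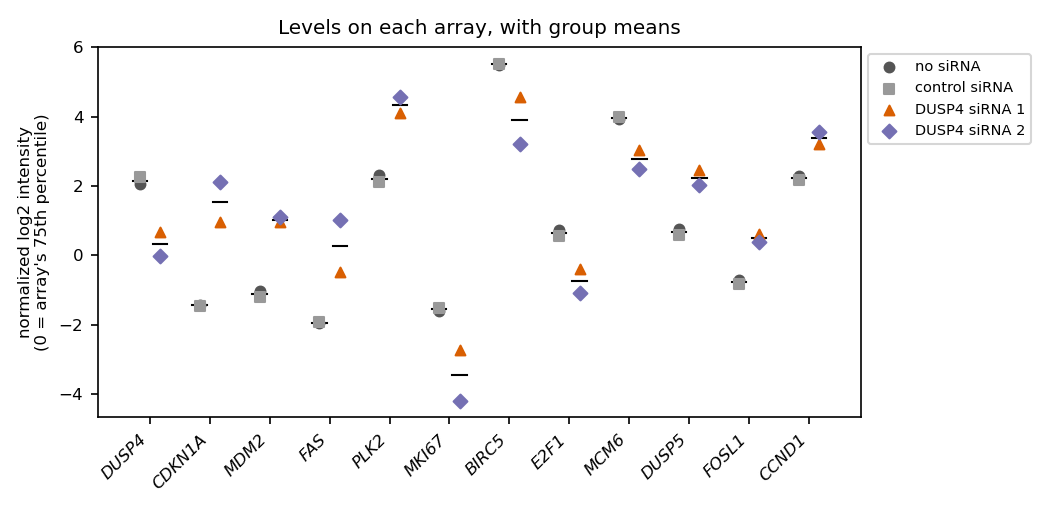
Normalized log2 intensity (vertical axis, 0 is the array's 75th percentile) of 12 genes on the 4 arrays, with control arrays to the left and DUSP4 siRNA arrays to the right of each gene, and black lines at the group means (n = 2). DUSP4, MKI67, BIRC5, E2F1 and MCM6 were lower on both DUSP4 siRNA arrays than on both controls, and CDKN1A, MDM2, FAS, PLK2, DUSP5, FOSL1 and CCND1 were higher.

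The comparison of knockdown with control asked which other genes differed when DUSP4 was reduced. At least 2-fold differences in all 4 knockdown-control array pairs were found for 396 of 16528 genes, 174 higher and 222 lower in the knockdown. Among them, the cell-cycle inhibitor CDKN1A was higher and the matrix glycoprotein SPARC was lower. In simulated data 63 of 16284 unchanged genes met this rule. The other splits of the 4 arrays into pairs gave 2 genes and 1 gene, counts that are low by construction, since a gene altered on both knockdown arrays cannot enter them. In 55.8% of genes the groups did not overlap, where chance gives 33.3%. No gene passed limma's adjusted p of 0.05 (smallest 0.0749), while 3212 genes had an unadjusted p under 0.05, 1624 higher and 1588 lower, against 826.4 expected by chance. At an adjusted p of 0.10 there were 55 genes, 29 higher and 26 lower. A permutation of 2 against 2 arrays cannot give an exact two-sided p below 0.333. The count at 0.05 turned on the spread between the DUSP4 siRNA arrays. It was 5854 without the siRNA 1 array and 2749 without the siRNA 2 array, and stayed at 0 without either control array. With fewer array pairs to meet, the count of genes at least 2-fold apart was 2143 without the siRNA 1 array, 873 without the siRNA 2 array, 713 without the no-siRNA array and 667 without the control-siRNA array. Under another background correction, normexp, it was 54 higher and 53 lower with all 4.

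The largest positive differences are described first. COL17A1, a collagen of hemidesmosomes, was higher by 3.39 (log2, SE 0.649, 10.5-fold), the keratin KRT13 by 2.61 (SE 0.358) and the keratin-associated KRTAP3-1 by 3.39 (SE 0.536). MYBPH, a myosin-binding protein, had the largest difference among genes well above background on all 4 arrays, 3.67, with an SE of 1.00 because its level differed between the DUSP4 siRNA arrays. CDKN1A, the cyclin-dependent kinase inhibitor p21, was 7.88-fold higher (2.98, SE 0.412). GALNT5, an enzyme of mucin-type glycosylation, differed by 2.88 with an SE of 0.173, and the hyaluronan synthase HAS3 by 2.81 (SE 0.386). The aldo-keto reductases AKR1B15 and AKR1B10 differed by 2.70 and 2.55. These are near-identical paralogs, so their probes may share signal and the separate values are uncertain. PRDM1, a transcriptional repressor, differed by 2.48 (SE 0.537), and the aquaporin pseudogene AQP7P3 by 2.46 (SE 1.09), with the same reservation about paralogs. Against the control mean AQP7P3 was at 0.85 on the siRNA 1 array and 4.08 on the siRNA 2 array. XDH, KRT6A and KRT34 were not well above background on either control array and were at least 6.85-fold, 6.67-fold and 5.04-fold higher in the knockdown in the processed signal. These bounds do not hold under normexp, which adds an offset of 50 to all intensities, where the log2 differences were 0.88, 0.99 and 0.86. Normexp also gave smaller differences for KRTAP3-1 (2.16), COL17A1 (1.67), AKR1B10 (1.49), KRT13 (1.48), PRDM1 (1.36) and AKR1B15 (0.95). The limma adjusted p of these genes ranged from 0.0749 for KRT34 to 0.308 for AQP7P3. Of 141 genes examined singly under the alternatives, 53 had a log2 difference over 1.5 times smaller under normexp, and 6 with the mean of a gene's probes.

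The largest negative differences follow. The collagen-uptake receptor MRC2 was lower by a log2 difference of -2.42 (SE 0.249, 5.35-fold) and SPARC by -2.42 (SE 0.318). GLI1, a transcription factor of hedgehog signalling, differed by -2.29 (SE 0.189), the nerve growth factor receptor NGFR by -2.16 (SE 0.487) and the class II histocompatibility gene HLA-DPB1 by -2.19 (SE 0.163). Among genes well above background on all 4 arrays, RDM1, a DNA repair protein, had the largest negative difference, -2.70 (SE 0.507), followed by the spectrin SPTB at -2.60 (SE 0.611). LYPD6, RTKN2, PALM3, TMSB15A and APOLD1 differed by between -2.20 and -2.04. IL21R, NCAM1 and TMEM270 were not well above background on either knockdown array and were at least 8.70-fold, 4.10-fold and 3.68-fold lower there in the processed signal, while under normexp the log2 differences were -1.24, -0.70 and -0.53. Normexp also gave smaller differences for GLI1 (-1.49), NGFR (-1.30), RTKN2 (-1.20), LYPD6 (-1.17), APOLD1 (-1.0), SPARC (-0.95) and HLA-DPB1 (-0.77). Their limma adjusted p ranged from 0.0749 for NCAM1 to 0.238 for LYPD6 among all 15 genes named here as lower. Most genes of largest difference named so far had no other probe well above background on all 4 arrays. Where there was one, its difference had the same sign, as for HAS3, with 1.03, and LYPD6, with -1.56. Other probes were not examined singly for the list members named below.

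**Figure D2:**
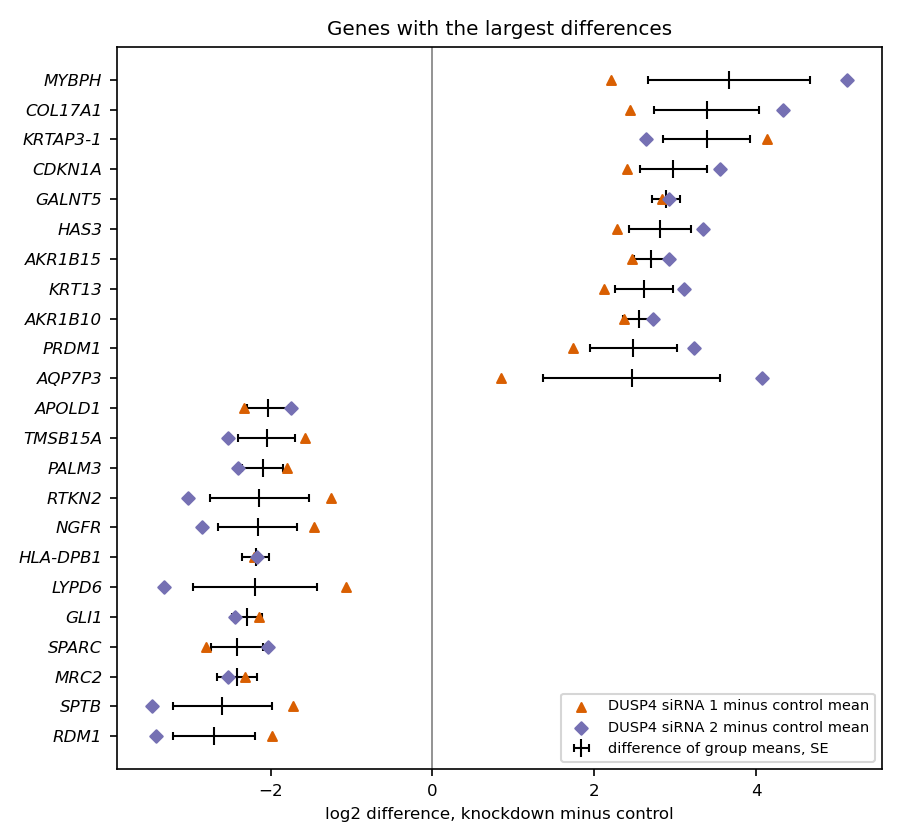
Log2 difference between knockdown and control (horizontal axis) for 11 of the 12 highest and the 12 lowest genes well above background on all 4 arrays, as the difference of group means with its SE (black) and as each DUSP4 siRNA array minus the control mean (coloured points). None of the 23 genes shown passed an adjusted p of 0.05. Both siRNA arrays lie on the same side of 0 for each, which the choice of genes without overlap between groups required.

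Targets of the tumour suppressor p53 were the group with the largest positive shift. Of 26 measured targets 25 had a positive difference, with a mean of 1.17 ± 0.76 (log2, SD over genes). CDKN1A was followed by TP53I3 (2.35, SE 0.647), the death receptor FAS (2.21, SE 0.525) and MDM2 (2.13, SE 0.163, and 1.39 with the mean of its probes), the ubiquitin ligase that limits p53. Camera, a competitive test of a gene list in limma, was run on all 30 lists with a preset correlation of 0.01 between genes, and called this shift at an adjusted p of 8.58e-11. With an estimated correlation it was not called (adjusted p = 0.601 with an estimated correlation), and neither was any other of the 30 lists. That form of camera rests on the 2 residual degrees of freedom, so it has little power here. The preset form instead takes genes as nearly independent, although the estimated correlation of p53 targets was 0.294. Its small p-values rest on the spread over genes, which are not replicates, and can overstate the evidence. Lists with a negative estimated correlation lost their call too, such as AP-1 family and stress early genes (-0.035). Over all genes tested 0 of the 26 targets passed limma's 0.05, 20 had an unadjusted p under 0.05, and 16 passed adjusted over the list alone. Apoptosis regulators lay higher too, with 24 of 30 positive and a mean of 0.42 ± 0.57 (camera, adjusted p = 0.00248, and adjusted p = 0.620 with an estimated correlation). The BH3-only gene BIK and the death receptor gene TNFRSF10A differed by 1.51 (SE 0.636) and 1.43 (SE 0.169). BIK ranged from 0.59 to 2.44 over the alternatives. CASP10 differed by 1.15 (0.28 with the mean of its probes) and the inhibitor of apoptosis BIRC3 by 1.11. In this list 5 genes passed limma's 0.05 adjusted over the list alone, TNFRSF10A, PMAIP1, CFLAR and BAK1, which were higher, and BCL2, which was lower (-0.94, SE 0.198).

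Genes of DNA replication and mitosis lay lower. All 30 genes of G2/M and mitosis were lower on both DUSP4 siRNA arrays than on both controls, with a mean of -1.39 ± 0.23 (log2, SD over genes). MKI67, a marker of cycling cells, differed by -1.91 (SE 0.505), CDC25C by -1.77 (SE 0.715), DLGAP5 by -1.66 (SE 0.435) and KIF2C by -1.65 (SE 0.785). The array labelled siRNA 2 carried most of the size. The list's mean was -2.08 without the siRNA 1 array and -0.70 without the siRNA 2 array, with -2.81 and -0.72 for CDC25C, -2.81 and -0.50 for KIF2C, and -2.27 and -1.04 for DLGAP5. MKI67 was at -1.08 under normexp. Camera called this list at an adjusted p of 8.58e-11, and did not call it with an estimated correlation, which was 0.99 (adjusted p = 0.791 with an estimated correlation). The lost call cannot be put down to that correlation alone, since lists with a negative one lost theirs too. In limma 0 of them passed adjusted over the list alone and 18 had an unadjusted p under 0.05. Of 29 genes of G1/S and DNA replication 28 were lower, with a mean of -0.93 ± 0.38. The adjusted p was 3.52e-10 by camera, and 0.791 by camera with an estimated correlation, which was 0.95. Here too the siRNA 2 array carried more of the size. The list's median against the control mean was -0.53 on the siRNA 1 array and -1.47 on the siRNA 2 array. The G1/S transcription factor E2F1 differed by -1.38 (SE 0.282), GINS2 of the replicative helicase by -1.36 (SE 0.294) and RFC4 by -1.20 (SE 0.270). In that list 9 genes passed limma's 0.05 adjusted over the list alone. The list of CDK inhibitors and G1 cyclins, which pools opposing functions, had no shift (limma camera adjusted p = 0.895). In it 3 of 17 passed limma's 0.05 adjusted over the list alone, all of them higher: CDKN1A, CCND1 (1.13, SE 0.189) and CDK6 (1.10, SE 0.148). In contrast, CDKN2C differed by -1.60 (SE 0.459). CDKN2B was not well above background on either control array and was at least 1.82-fold higher in the processed signal (0.26 under normexp).

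The signalling layer closest to DUSP4 was covered by several lists. ERK pathway output was higher by a mean of 0.38 ± 0.72 (log2, SD over genes), with 20 of 26 genes positive (camera, adjusted p = 0.0234, and adjusted p = 0.791 with an estimated correlation). HMGA2 differed by 1.98 (SE 0.661), but by 0.32 with the mean of its probes, DUSP5, a phosphatase of ERK, by 1.57 (SE 0.205), the AP-1 subunit FOSL1 by 1.28 (SE 0.168) and cyclin D1, CCND1, by 1.13 (SE 0.189). In this list 6 genes passed limma's 0.05 adjusted over the list alone. The 6 negative members were PHLDA1 (-0.78), ETV4 (-0.78), EGR1 (-0.68), FOS (-0.58), IER3 (-0.29) and SPRY4 (-0.26). DUSP6 and SPRY2 differed by only 0.16 and 0.13. These members were added after their values were seen. ERK output was thus higher on average, but not in every member. The other MAP kinase phosphatases were higher by a mean of 0.39 ± 0.54 in 11 of 14 genes (camera, adjusted p = 0.0234, and adjusted p = 0.601 with an estimated correlation). DUSP5 was followed by DUSP14 (1.10, SE 0.175), DUSP7 (0.79, SE 0.347, well above background on 1 control array) and DUSP18 (0.68, SE 0.158). Of these, DUSP5, DUSP14 and DUSP18 passed adjusted over the list alone. The AP-1 family and stress early genes were higher by a mean of 0.59 ± 0.60 in 16 of 18 genes (camera, adjusted p = 0.00248, and adjusted p = 0.601 with an estimated correlation). BTG2 differed by 2.05 (SE 0.811), FOSB by 1.24 (SE 0.200), ZFP36 by 1.11 (SE 0.172) and JUN by 0.98 (SE 0.220), and 5 genes passed adjusted over the list alone. Against the control mean BTG2 was at 0.86 on the siRNA 1 array and 3.24 on the siRNA 2 array. The MAP kinases and their kinases themselves had a mean of 0.00 ± 0.36 (limma camera adjusted p = 0.898). None of the 21 passed limma's 0.05 adjusted over the list alone and 3 had an unadjusted p under 0.05. MAPK11 (0.67) and MAP2K3 (0.65) had the largest differences, followed by MAPK12 (-0.52) and NRAS (-0.48). The limma camera call for ERK pathway output ended without the siRNA 2 array (adjusted p = 0.216), without a filter on dim probes (adjusted p = 0.157) and without spots at the arrays' low-numbered edge (adjusted p = 0.0632). The limma camera call for the phosphatases ended without the siRNA 1 array (adjusted p = 0.213) and without a filter on dim probes (adjusted p = 0.149). In these 2 settings the mean of the phosphatases was 0.49 and 0.42. They were the 1 list that limma's fry test called in 1 direction (fry, adjusted p = 0.0229). ERK pathway output had a mean of 0.38 without the filter, 0.36 without the edge and 0.17 without the siRNA 2 array. Under normexp FOSB was at 0.43, DUSP7 at 0.26 and DUSP18 at 0.20.

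Targets of YAP and SRF, and integrins and laminins, were called higher. The YAP and SRF targets had a mean of 0.49 ± 0.61 (log2, SD over genes), with 16 of 19 positive (camera, adjusted p = 0.00832, and adjusted p = 0.601 with an estimated correlation). The matricellular genes CCN2 and CCN1 differed by 1.59 (SE 0.395) and 1.29 (SE 0.494), FHL2 by 1.49 (SE 0.461) and tissue factor, F3, by 1.17 (SE 0.456). In limma 0 of them passed adjusted over the list alone and 6 had an unadjusted p under 0.05. Integrins and laminins had a mean of 0.49 ± 0.65 with 13 of 16 positive (camera, adjusted p = 0.0269, and adjusted p = 0.791 with an estimated correlation). The laminin chains LAMB3 (1.75, SE 0.240) and LAMA3 (1.70, SE 0.221) passed limma's 0.05 adjusted over the list alone, and the integrins ITGB4 and ITGA2 differed by 1.11 and 0.99. Under normexp LAMA3 was at 0.99, CCN2 at 0.84 and ITGA2 at 0.30. The limma camera call for YAP and SRF targets ended without the siRNA 1 array, where the mean was 0.43. That for integrins and laminins ended without the siRNA 2 array, where the mean was 0.32. It also ended without a filter on dim probes (limma camera adjusted p = 0.157), where the mean stayed at 0.49. Extracellular proteolysis and invasion genes went both ways, 11 positive and 10 negative (limma camera adjusted p = 0.685). The serpin SERPINB5 was higher by 1.30 (SE 0.210), and the interstitial collagenase MMP1, not well above background on either control array, was at least 3.94-fold higher in the processed signal (log2 difference 0.59 under normexp). TIMP3 was not well above background on either knockdown array and was at least 1.73-fold lower (-0.18 under normexp). In this list 3 of 21 passed limma's 0.05 adjusted over the list alone.

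A stress list and a lipid list were called lower. Endoplasmic reticulum and integrated stress genes had a mean of -0.36 ± 0.64 (log2, SD over genes), with 20 of 25 negative (camera, adjusted p = 0.00346, and adjusted p = 0.601 with an estimated correlation). The serine synthesis enzyme PHGDH differed by -1.98 (SE 0.575), CHAC1 by -1.36 (SE 0.337) and asparagine synthetase, ASNS, by -1.27 (SE 0.315), whereas the phosphatase subunit PPP1R15A was higher by 1.03 (SE 0.245). None passed limma's 0.05 adjusted over the list alone and 11 had an unadjusted p under 0.05, of which 8 were lower and 3 higher. Cholesterol synthesis genes had a mean of -0.21 ± 0.45 with 17 of 24 negative (camera, adjusted p = 0.0305, and adjusted p = 0.809 with an estimated correlation). INSIG1 differed by -1.36 (SE 0.266) and EBP by -0.71. In limma 0 passed adjusted over the list alone and 5 had an unadjusted p under 0.05. This last limma camera call ended without the no-siRNA array, the control-siRNA array or the siRNA 1 array. The mean was about as large without either control array (-0.22 and -0.21), but only -0.07 without the siRNA 1 array.

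Markers of other cell types were included because a culture can hold other cells. Of 14 fibroblast markers 5 were measured, with a mean of -0.89 ± 0.80 (log2, SD over genes; camera, adjusted p = 0.0223, and adjusted p = 0.601 with an estimated correlation). FBLN1 and C1R differed by -1.81 (SE 0.480) and -1.36 (SE 0.160), C1S by -0.15, and PDGFRB, not well above background on either knockdown array, was at least 1.18-fold lower (-0.12 under normexp). FBLN1, C1R and PDGFRB passed limma's 0.05 adjusted over the list alone. The limma camera call ended under normexp (adjusted p = 0.107), without a filter on dim probes (adjusted p = 0.817) and with a stricter filter (adjusted p = 0.0745). In these settings the mean was -0.60, -0.22 and -0.82. It ended too without the siRNA 2 array, where the mean was -0.70. Blood and immune cell markers had no shift (11 of 17 measured, limma camera adjusted p = 0.511). Of them CD68, a lysosomal protein, differed by 2.15 (SE 0.257) and was the 1 gene past limma's 0.05 adjusted over the list alone, while CSF1R differed by -1.26 (well above background on 1 knockdown array) and HLA-DRA by -0.87. Under normexp these 3 were at 1.22, -0.28 and -0.29. CD3D was not well above background on either control array and was at least 1.84-fold higher (0.23 under normexp).

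The remaining 14 lists did not pass camera's 0.05. Hypoxia and glycolysis came to pass it without a filter on dim probes (limma camera adjusted p = 0.0468, mean -0.20). They also did without the no-siRNA array (mean -0.38), and fatty acid synthesis without the siRNA 2 array (mean -0.35). TGF-beta and BMP targets had an adjusted p of 0.294, and 5 of 16 genes passed limma's 0.05 adjusted over the list alone. ID2 and ID3, targets of BMP signalling, differed by -1.60 (SE 0.159) and -1.03 (SE 0.165). SMAD6 differed by -1.39 (SE 0.625), and ranged from -2.30 to -0.49 over the alternatives. WNT targets had an adjusted p of 0.685 with 6 of 16 past adjusted over the list alone. In the processed signal TNFRSF19 was at least 3.56-fold higher and NOTUM at least 2.40-fold lower (0.43 and -0.30 under normexp), and EPHB3 differed by -1.12 (SE 0.276). EGF receptor family and ligands had a limma camera adjusted p of 0.895 with 6 of 16 past adjusted over the list alone. NRG1 differed by 1.77 (SE 0.489), HBEGF by 1.12 (SE 0.262) and ERBB2 by -0.63 (SE 0.169). The list also held FGFR2, a receptor of another family, which differed by -1.01 (SE 0.216). Fatty acid synthesis genes (limma camera adjusted p = 0.307) held ACSL3 at -1.29 (SE 0.163), and NRF2 targets of oxidative stress (limma camera adjusted p = 0.781) held HMOX1 at 0.93 (SE 0.173) and AKR1B10. Mesenchymal genes (limma camera adjusted p = 0.685) held SPARC, vimentin, VIM, at -1.0 (SE 0.543) and smooth muscle actin, ACTA2, at 0.98 (SE 0.282). VIM ranged from -1.74 to -0.26 over the alternatives. Epithelial junction and keratin genes (limma camera adjusted p = 0.739) held KRT8 at 1.24 (SE 0.221) and the claudin CLDN3 at -1.01 (SE 0.177). Intestinal differentiation genes (limma camera adjusted p = 0.796) held KRT20 at -1.28 (SE 0.217, well above background on 1 knockdown array). Short-interfering RNA machinery genes had a limma camera adjusted p of 0.511 and held TNRC6C at 0.93 (SE 0.147, and 0.53 with the mean of its probes). In limma's fry test for differences in either direction they had the smallest adjusted p of the 30 lists (0.000759). That test passed 22 lists, reference genes among them (fry, adjusted p = 0.0496), so passing it sets a list little apart. Under normexp EPHB3 was at -0.56 and KRT20 at -0.22. In the lists of this paragraph so far, the counts past adjusted over the list alone that were not given lay at 1 or 2. Hypoxia and glycolysis (0.469), heat shock (0.75), NF-kB targets (0.898), interferon-stimulated genes (0.920) and reference genes (0.685) had no gene past limma's 0.05 adjusted over the list alone, with 6, 1, 2, 7 and 3 genes at an unadjusted p under 0.05. Members with large differences in these 5 lists, whether or not they had such a p, were ANKRD37 (-1.30), NDRG1 (1.27), the co-chaperone BAG3 (0.51), CXCL8 (-1.31, well above background on 1 knockdown array), BST2 (-1.39), IFIT3 (0.87) and the reference gene HPRT1 (-0.75). Mean, median and test differed in sign for interferon-stimulated genes, NF-kB targets, reference genes, NRF2 targets, CDK inhibitors and G1 cyclins, and MAP kinases and their kinases.

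**Figure D3:**
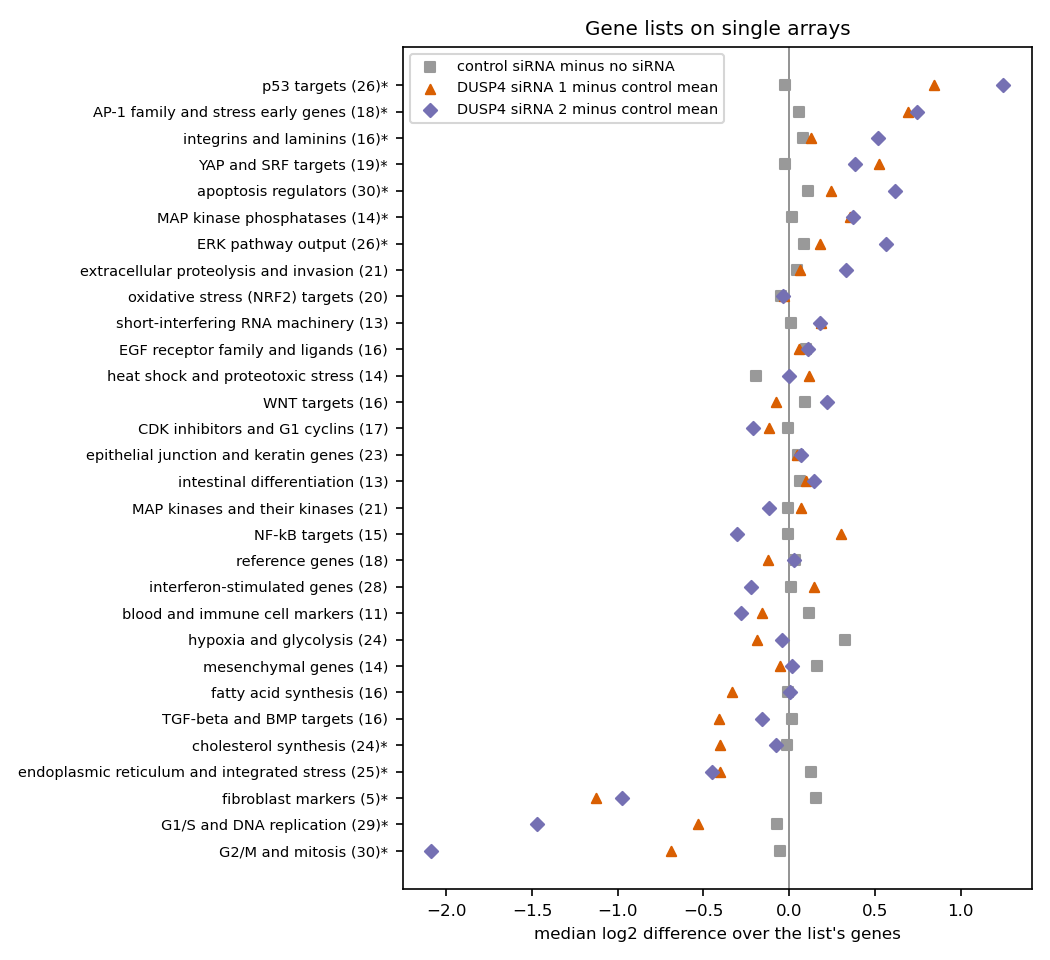
Median log2 difference over the measured genes of each of 30 lists (horizontal axis), on the control-siRNA array against no siRNA and on each DUSP4 siRNA array against the control mean. The number of measured genes stands in parentheses, and an asterisk marks the 12 lists that camera called for knockdown against control with a preset correlation. For G2/M and mitosis the medians were -0.69 and -2.09 on the DUSP4 siRNA arrays and -0.05 on the control-siRNA array.

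The comparison of control siRNA with no siRNA addressed transfection with an unrelated siRNA. With 1 array each it cannot separate an effect of transfection from an effect of the array. A difference of at least 2-fold was found for 120 genes, 76 higher and 44 lower with control siRNA. The largest positive differences were those of ZNF763 (5.12), the proteasome assembly factor POMP (4.16), thymidine phosphorylase, TYMP (3.68), DYRK1B (2.65) and PTPN4 (2.63). For each of these 5 genes the no-siRNA array alone was low and the other 3 arrays lay close together, as for POMP (-3.94 against 0.22, 0.26 and 0.40). The spots of 4 of them, POMP, TYMP, DYRK1B and PTPN4, lie in the first 10 of the array's 85 columns, on the low-numbered side, and that of ZNF763 lies near the other side, in column 84. With those first 10 columns left out on all arrays the count was 91, 47 higher and 44 lower, without the excess of higher genes. The largest negative differences were those of AOC2 (-2.51), CNN1 (-1.64), FSTL5 (-1.58), JPH2 (-1.54) and ODF1 (-1.52). Under normexp the count was 22, all of them higher. Hypoxia and glycolysis genes had a median of 0.33, above all of 10000 random lists matched on signal, and heat shock genes a median of -0.19, below all of them. For p53 targets the median was -0.03, at percentile 5.88. G1/S and DNA replication genes had a median of -0.07 (percentile 0.01) and G2/M and mitosis genes -0.055 (percentile 0.47), small shifts in the direction of the knockdown. Apoptosis regulators had a median of 0.11 (percentile 99.75), also in the knockdown's direction, where their median was 0.40. Endoplasmic reticulum and integrated stress genes had a median of 0.13 (percentile 99.94), against the knockdown's direction.

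Between the DUSP4 siRNA arrays, 1560 genes were at least 2-fold apart, again with 1 array each and no replicate check. The array labelled siRNA 1 was higher at 826 and lower at 734, a balance that turned under median centring (766 and 808). The deposited table gave 711 and 840 by its column labels, which stand the other way round from the scanner files. Which siRNA each of these arrays carried is not settled, because the deposited value table assigns them the other way round. On the array labelled siRNA 1 the largest excesses over siRNA 2 were those of the carbonic anhydrase-related CA8 (3.64), CT45A5 (2.96), the chemokine CXCL1 (2.83), KRT6A (2.83) and LCP1 (2.71). KRT32 (-4.07), SCG2 (-3.31), AQP7P3 (-3.23), AHNAK (-3.17) and MYBPH (-2.92) lay lowest. CT45A5 and KRT6A have near-identical paralogs, so their values are uncertain. G2/M and mitosis genes had a median of 1.35 for siRNA 1 minus siRNA 2, above all matched random lists, and p53 targets a median of -0.47, below all of them.

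The differences from the control mean went largely the same way under both siRNAs. Relative to control, 423 genes were at least 2-fold higher and 554 lower on the siRNA 1 array, and 952 and 1294 on the siRNA 2 array. Of these, 262 were higher on both and 276 lower on both, where independent lists would share 24.4 and 43.4. Both differences use the same control arrays, and simulated unchanged groups, with the spread of the control arrays, gave 14.4 and 13.7. With the control arrays split, 1 for each siRNA, the differences share no array, and 229 and 271 genes were shared one way (26.6 and 41.7 if independent) and 211 and 282 the other way (26.3 and 49.8). Across the 16528 genes, which are not independent replicates, Pearson's r between the 2 sets of differences was 0.58 and Spearman's rho 0.51, and 67.6% of genes had the same sign. The simulated unchanged groups gave r = 0.33 and 60.8% with the same sign. The covariance was 0.225 against a simulated 0.0165. With the control arrays split, r was 0.53 and 0.49, and 66.1% and 64.1% of genes had the same sign.

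**Figure D4:**
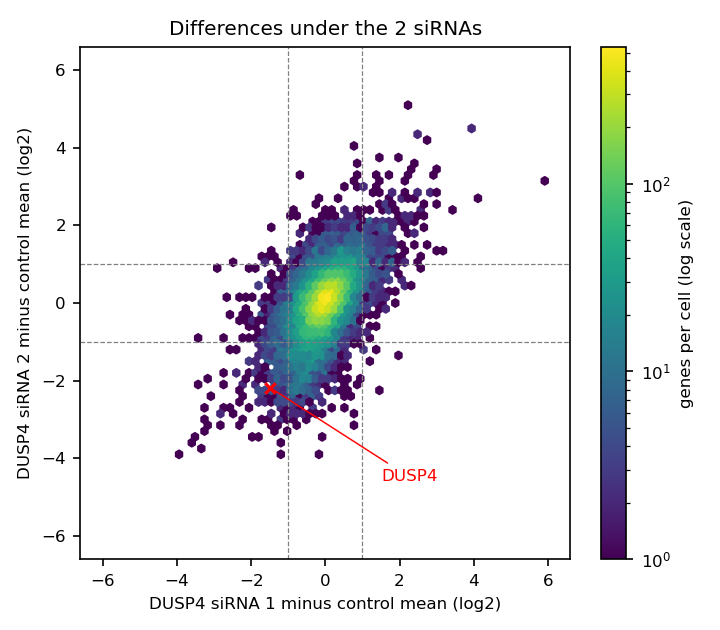
Log2 difference from the control mean on the array labelled DUSP4 siRNA 1 (horizontal axis) and siRNA 2 (vertical axis) for 16528 genes, as the number of genes per hexagon on a log colour scale, with dashed lines at 2-fold and DUSP4 marked in red. Most genes lie near 0 on both axes, and Pearson's r across genes is 0.58.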

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

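The tests of column exchange and of a single siRNA acting alone on replication and mitosis genes were chosen after the result was seen.

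Interferon-stimulated genes had medians of opposite sign under the DUSP4 siRNAs relative to both control arrays (against the control mean 0.15 for siRNA 1, inside matched random lists, and -0.22 for siRNA 2, outside them), with a median of 0.33 (log2) for the array labelled siRNA 1 minus that labelled siRNA 2 (matched random lists -0.24 to 0.21), and with 1 array each the difference between the siRNAs was not tested against replicates.

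In the deposited value table, which no comparison here uses as its main source, the column for siRNA 1 followed the scanner values of the other DUSP4 siRNA array (r = 0.988), and so did the column for siRNA 2 (r = 0.986). Their correlations with their own scanner values were 0.0552 and 0.0528, against 0.981 and 0.980 for the control columns. An exchange of the columns or of the scanner files may account for this, since the lower match to the other sample was 0.986. Another normalization by the authors is argued against, because under normexp the higher correlation with the own scanner values was 0.10. The control columns reached only 0.637 and 0.649 there, short of the level set in advance, so the close match to the other sample carries the argument, and which of the files is right stays open, with no biological explanation tested.

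p53 targets were higher and genes of replication and mitosis lower on the DUSP4 siRNA arrays than on the controls. The control-siRNA array did not carry a pattern of this size relative to the no-siRNA array. There the median of p53 targets was -0.027 (knockdown 0.91) and that of the 59 replication and mitosis genes -0.0607 (knockdown -1.18). The latter lay beyond matched random lists (-0.0208 to 0.0615) and in the knockdown's direction but was far smaller. With 1 array each, transfection cannot be separated from the array, so its part in the DUSP4 siRNA cultures is not settled. A pattern on 1 DUSP4 siRNA array alone is argued against. The smaller of the medians was 0.85 for p53 targets and -0.61 for replication and mitosis genes. Both lay beyond the central 95% of matched random lists (-0.15 to 0.15 and -0.11 to 0.10). These random lists do not allow for genes that vary together, and the medians of both siRNA arrays use the same control mean. A response to reduced DUSP4 may account for the pattern, as a hypothesis found and examined on the same data. Effects of both siRNAs on transcripts other than DUSP4, and differences between cultures, were not tested and stay open.

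The DUSP4 siRNA arrays were at least 2-fold apart at many more genes than the control arrays, 1560 against 120. Dim and noisy probes are argued against, because among the 4132 brightest genes the counts were 185 and 9, a ratio of 20.6. A difference in brightness or scaling is argued against too, because after quantile normalization the counts were 1537 and 121, a ratio of 12.7. A stronger effect of 1 siRNA, on DUSP4 or on other transcripts, may account for it, and with 1 array per siRNA a difference between cultures stays open too.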

How the results depend on the processing

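The alternative without the columns at the low-numbered edge was chosen after the data were seen. DUSP4 was lower in every alternative run, with adjusted p from 0.00388 to 0.671, and no gene passed limma's 0.05 under any normalization, filter, probe, prior or edge alternative (2980 to 4033 genes at an unadjusted p under 0.05). Genes at least 2-fold apart in all 4 array pairs numbered 1.1e+02 under normexp (54 higher and 53 lower), 1385 at 1.5-fold and 101 at 3-fold. Between the control arrays the counts were 22 under normexp, 1375 without a filter, 58 with the stricter filter, 409 at 1.5-fold and 46 at 3-fold. Between the DUSP4 siRNA arrays they were 577 under normexp, 3011 without a filter, 4217 at 1.5-fold and 402 at 3-fold. The fold minimums and filters change these counts by construction, and for normexp the cause was not tested. At an adjusted p of 0.10, 55 genes passed limma. Of 30 lists 12 were called by camera, and 0 with an estimated correlation, a test on 2 residual degrees of freedom. Fry called 1 list in 1 direction, the MAP kinase phosphatases (fry, adjusted p = 0.0229), and 22 in either direction. Of the 12, 8 kept their call in all 7 normalization, filter and probe alternatives and 6 without each array in turn, and the same 6 kept both. Leaving out each array in turn gave DUSP4 differences of -2.19 to -1.48, counts past adjusted p 0.05 of 0 to 5854, 2-fold counts of 667 to 2143 (fewer pairs to meet) and 9 to 12 lists. With 1 array left in a group, that array is assumed to vary like the other group. The counts of 5854 and 2749 arose without the arrays labelled siRNA 1 and siRNA 2, because the spread between them no longer entered the variance. Reversed without 1 array were NRAS (-1.44 to 0.49), CXCL1 (-2.04 to 0.79), CA2 (-1.44 to 0.46), HSPA1B (-0.052 to 0.53) and C1S (-0.67 to 0.38), since the DUSP4 siRNA arrays differed in sign. HSPA1B and C1S also reversed without the control-siRNA array (-0.022 and 0.063), and there the cause was not tested. With the deposited table, siRNA 1 minus siRNA 2 reversed for CA8 (-3.65), CT45A5 (-2.97), CXCL1 (-2.84), KRT6A (-2.84), LCP1 (-2.72), KRT32 (4.06), SCG2 (3.29), AQP7P3 (3.22), AHNAK (3.16) and MYBPH (2.91), as its 2 columns follow the other array. For 141 named genes, 1451 of 1673 values kept direction and side of the threshold, 215 came to pass it, all without a knockdown array and so with 1 array in that group, and 7 reversed. Their log2 differences were over 1.5 times smaller for 53 genes under normexp, 37 without the siRNA 2 array and 10 without the siRNA 1 array. The correlation between the siRNAs ran from 0.49 to 0.58. Dim probes add to the counts between single arrays, as the counts without a filter show. No paired analysis was possible because the labels pair no samples, and the slide block was not run because there was 1 slide.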

Other observations

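The gene families and the spots described here were chosen after their values were seen. Of 26 keratin genes measured, 18 had a positive difference between knockdown and control (17 under quantile normalization and under normexp), and 5 were at least 2-fold higher in all 4 array pairs with 0 lower. Of these 5, KRT6A and KRT34 were not well above background on either control array, and KRT16 was on 1 only. Under normexp KRT6A and KRT34 were at 0.99 and 0.86 (log2). The median of the 26 was 0.28, and 13 had an unadjusted p under 0.05 in limma while 0 passed an adjusted p of 0.05. Of 14 HLA class II genes, 1 had a positive difference under every scaling and 12 were lower without overlap between groups, where 55.8% of all genes did not overlap in either direction and chance gives 33.3%. HLA-DRB1, HLA-DRB3, HLA-DRB4 and HLA-DRB5 are close paralogs, so their probes may share signal and the 14 genes are not separate measurements. The median of the 14 was -0.50, and 8 had an unadjusted p under 0.05 in limma. HLA-DPB1 was at -2.19, HLA-DOA at -1.97 and HLA-DRA at -0.87. Under normexp HLA-DPB1 and HLA-DRA were at -0.77 and -0.29.

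On the no-siRNA array, 40 of 25789 spots lay more than 1 (log2) below the other arrays where those lay within 0.5 of one another. Of these 26 (65.0%) lay in the first 10 columns, at the low-numbered side of the array, which hold 11.1% of the spots. The same counts were 3 and 0 on the control-siRNA array, 110 and 9 on the siRNA 1 array, and 608 and 65 on the siRNA 2 array.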
